A study of Taeniopygia guttata with 48 samples.

How the data were processed

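Zebra finch eggs were injected with 500 pg of testosterone in 5 µl of peanut oil, or with the oil alone, and brain tissue was taken from the birds as adults. Per the labels' protocols, frozen brains were sectioned at 50 µm and the hypothalamus and the nucleus taenia of the amygdala were taken with a 1 mm punch. Strand-specific mRNA libraries were then made with a KAPA kit. The 24 RNA libraries form 8 groups of 3, by region, sex and treatment. The 24 methylation samples of the series were not analysed here. The labels mark the libraries of a group as separate samples and do not state that each came from its own bird, so p-values measure the spread between these samples.

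The deposited values are FPKM (fragments per kilobase of transcript scaled to a fixed number of mapped fragments), which the authors computed for 17475 genes. Per the submitters' processing notes, cutadapt 1.9.1, TopHat2 2.1.1 and Cufflinks 2.2.1 were used. The genome build and the annotation are not given in the sources used here. The table held 0 columns that could not be tied to a sample. FPKM divides out the sequencing depth and the gene length, so a few very abundant genes can lower all other values of a library, and the read number behind a value is lost.

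Absolute depth is therefore unknown. Relative depth was estimated from the steps of low values. Where whole reads are counted, the commonest ratio of values under 0.2 FPKM between 2 libraries is the ratio of their depths. This ratio was taken for all 276 pairs of libraries, from 62 to 262 genes a pair, and 1 depth per library was fitted to them. Of the 69 pairs with the sharpest peak, 71.0% lay within 3% of the fitted depths, and 5.4% when their ratios were shuffled. The depths had been fitted to these same pairs and were not fitted again after shuffling, so the 2 shares are not a like comparison. Of all pairs, 35.9% lay within 3%, so the estimates are rough.

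The gene identifiers were of the Ensembl type, with no symbols. The gene table at hand (assembly bTaeGut7.mat) matched 0 of them, so no gene could be named and no chromosome given. The gene lists fixed before the data were examined, and the rule that named genes by symbol, could not be applied. In their place, the 2 identifiers with the largest rise and the 2 with the largest fall are printed for the only contrast with genes past the threshold.

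Tests were made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). Fold changes on this scale understate the change of low genes. A gene was tested when its mean FPKM over the libraries of the fit was at least 1. The 11 contrasts, the filter and most alternatives were fixed before the data were examined. A model with 1 mean per group was fitted to the 12 libraries of a region for treatment, sex and their interaction, and to all 24 libraries for region and its interactions. Variances were moderated with a trend on mean expression, and p was adjusted by the Benjamini-Hochberg method within a contrast, at 0.05. A contrast of the sex difference between the regions was added after the data were seen. Figures were drawn with matplotlib 3.10.9.

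The alternatives were pseudocounts of 0.1 and 5, no filter, a minimum mean of 5 FPKM, median-ratio scaling, quantile normalization, library weights and robust moderation. Further ones were other sets of libraries in the fit, the replicate number as a block, and leaving out each library of the contrast in turn. Without 1 library a group has 2 left, and the pooled spread is used. Replicate numbers are shared between groups, so the deviations of same-numbered libraries from their group means were correlated across genes. In the female nucleus taenia all 3 pairs of testosterone and control libraries correlated above 0.1 (r = 0.171, 0.232 and 0.151), and by the rule fixed for this check the numbers were taken to pair those libraries, from the data alone. The labels give no meaning to the numbers. In sets not taken as paired, single same-numbered pairs reached r = 0.301 (male treatment, nucleus taenia) and 0.451 (sex, hypothalamus), so the pairing may be chance.

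The tests were tried on simulated data with the genes' own means and spread, 200 changed genes and 20 runs. The noise was independent between genes, and a gene had the same spread in every library. In the male hypothalamus treatment contrast, over 13569 genes, 35.9% of 4-fold changes and 1.6% of 2-fold changes were recovered. In the male nucleus taenia treatment contrast, over 13551 genes, the shares were 48.6% and 7.2%. In the nucleus taenia sex contrast, over 13551 genes, they were 73.2% and 29.3%, and in the region contrast, over 13612 genes, 90.6% and 55.5%.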

Results

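RNA was measured in the hypothalamus and in the nucleus taenia, the part of the avian amygdala that takes part in social behaviour, of adult zebra finches whose eggs had received testosterone or oil. Each of the 8 groups of region, sex and treatment had 3 libraries. Between 14285 and 15152 of the 17475 genes had a value above 0 in a library. Estimated depth ran from 0.58 to 1.39 times that of the median library. The geometric mean was 0.87 in the 12 testosterone libraries and 1.08 in the 12 control libraries, a difference that did not pass a two-sided permutation test within sex and region (p = 0.0528, 100000 resamples). In females the testosterone libraries were shallower than every control library in both regions, at 0.63 to 0.88 against 1.14 to 1.39 in the hypothalamus and 0.79 to 0.92 against 0.97 to 1.08 in the nucleus taenia.

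1 library stood apart from the others. The library labelled female testosterone hypothalamus replicate 3 had a mean Pearson r of 0.757 with the other 23 libraries, across 13612 genes, while the others had 0.844 to 0.915. Its median FPKM was 7.03, and 160 genes were listed at 0 in it although their median in the other libraries was at least 5 FPKM. In the other libraries 18 to 59 genes met that description. Its estimated depth was 0.69, and 3 libraries were shallower.

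**Figure D1:**
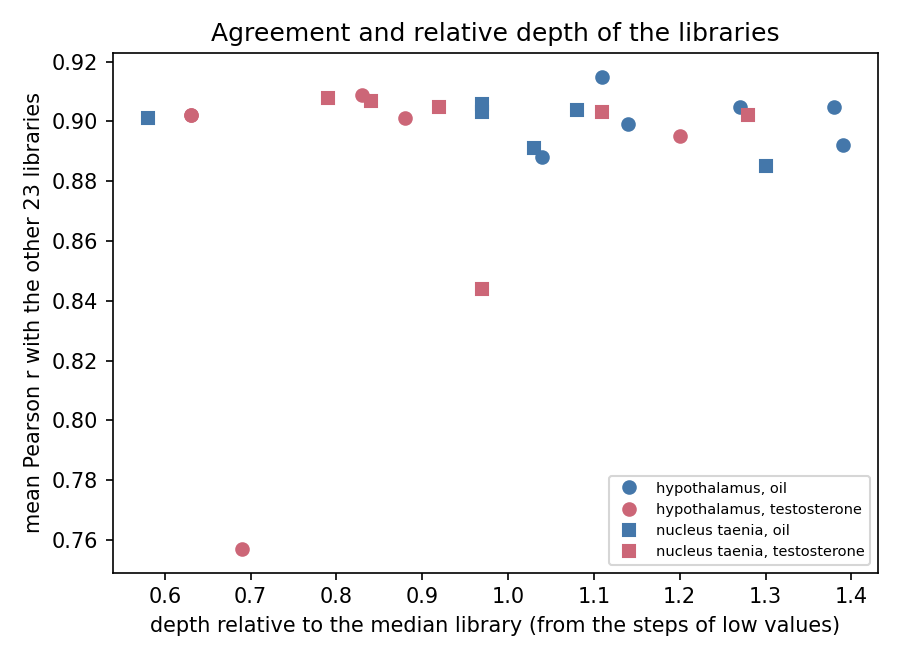
Mean Pearson r of each library with the other 23 (vertical axis) against its depth relative to the median library (horizontal axis). Points are single libraries, circles for hypothalamus and squares for nucleus taenia, coloured by treatment. The library at r = 0.757 is female testosterone hypothalamus replicate 3, and the next lowest, at 0.844, is male testosterone nucleus taenia replicate 2.

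The series asks how prenatal testosterone relates to gene expression in the adult brain. In the male hypothalamus, limma found 0 of 13569 genes past an adjusted p of 0.05 between testosterone and control birds, with 833 genes at an unadjusted p under 0.05, or 6.14%, where chance gives 5%. The smallest adjusted p was 0.752. The 95% interval of a gene's log2 difference had a median half-width of 0.905, equal to 1.87-fold. Of changes simulated in this contrast, limma recovered 1.6% at 2-fold and 35.9% at 4-fold, so changes of these sizes were mostly not detectable in this fit. The interval and the simulation used the spread pooled over the 12 hypothalamus libraries of both sexes. These include the library labelled female testosterone hypothalamus replicate 3, which was not left out of this fit singly. With the 6 male libraries alone the smallest adjusted p in limma was 0.219. The unadjusted count ran from 369, or 2.71%, without male testosterone replicate 1 to 1140, or 8.40%, without male testosterone replicate 3, and was 543 without male control replicate 1, so it was not steadily above chance. It was 1314 with the 6 libraries alone and 2512 with library weights. Leaving out male testosterone replicate 3 gave 17 genes past the adjusted threshold, and leaving out male testosterone replicate 2 or male control replicate 3 gave 1.

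In the female hypothalamus limma also found 0 genes, with 697 at an unadjusted p under 0.05 and a smallest adjusted p of 0.664. The same interval width applied. Without the library labelled female testosterone hypothalamus replicate 3 the count was 0, with 571 genes at an unadjusted p under 0.05. The unadjusted count was 2849 without testosterone replicate 1, 1395 with all 24 libraries in the fit and 245 with the 6 libraries alone. The adjusted count was 3 without testosterone replicate 1 and 2 without testosterone replicate 2, and 1 when only the 6 libraries of the comparison were fitted. Library weights gave 2146 genes, in a fit where the weight estimation stopped before convergence and 1 library had a weight of 241. The treatment difference between the sexes in the hypothalamus passed for 0 genes in limma, with 403 at an unadjusted p under 0.05, and with 249 to 937 when 1 library was left out (lowest without male testosterone replicate 1, highest without female testosterone replicate 1). It gave 18 genes with library weights, and 1 gene without female testosterone replicate 2, male testosterone replicate 2 or male testosterone replicate 3.

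In the nucleus taenia of males, limma found 0 of 13551 genes for treatment, with 378 at an unadjusted p under 0.05, or 2.79%. The unadjusted count was 1362 without male testosterone replicate 1 and 960 without male testosterone replicate 3. Leaving out male control replicate 1 gave 4 genes, and leaving out male control replicate 2 or male testosterone replicate 1 gave 1. In females limma found 0 genes, with 399 at an unadjusted p under 0.05, and 1 gene without female control replicate 2. The unadjusted count ran from 206 without female control replicate 3 to 918 without female control replicate 2. In a fit of the 6 libraries alone the count was 0, with 884 genes at an unadjusted p under 0.05. With the replicate number as a block in that fit, which the rule of the pairing check called for though the pairing may be chance, it was 0, with 1123. The median half-width of the interval was 0.794, equal to 1.73-fold. The treatment difference between the sexes gave 0 genes in limma, with 528 at an unadjusted p under 0.05 and a median half-width of 1.123, equal to 2.18-fold. The unadjusted count ran from 314 without female control replicate 3 to 1344 without male testosterone replicate 1, and leaving out 10 of the 12 libraries in turn moved it by over 1.5 times. The adjusted count was 1 gene without male control replicate 1, male control replicate 2 or male testosterone replicate 1.

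The sexes differed in the nucleus taenia. By limma's adjusted p, 134 of 13551 genes differed between the 6 male and the 6 female libraries, 126 higher in males and 8 lower. The median difference of the 126 genes was 1.01 on the log2 scale, and the lowest was 0.66. ENSTGUG00000016397 was at 26.2 ± 11.9 FPKM in males and 2.91 ± 3.40 in females (SD, n = 6 each; log2 difference 3.28, SE 0.63, limma adjusted p = 0.0357). ENSTGUG00000017058 was listed at 0 in every female library of both regions and was higher in the male nucleus taenia (limma adjusted p = 0.0317). Its values there were 67.5, 246 and 0 FPKM in control replicates 1 to 3 and 55.3, 97.3 and 287 FPKM in testosterone replicates 1 to 3. In the male hypothalamus it was listed at 0 in control replicates 1 to 3 and testosterone replicate 2, and was at 70.2 and 79.3 FPKM in testosterone replicates 1 and 3 (limma adjusted p for sex = 0.493). Among the genes lower in males, ENSTGUG00000015894 was at 1.23 ± 2.31 FPKM against 6.71 ± 1.73 (log2 difference −2.19, limma adjusted p = 0.0134). ENSTGUG00000008528 was at 2.95 ± 2.01 FPKM against 11.4 ± 4.12 (log2 difference −1.75, limma adjusted p = 0.0314). Each of the 4 lost its call when some single library was left out, as did 3 of them with the replicate block.

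The count of 134 depended on the libraries. It was 65 to 108 without any 1 female library or any 1 male control library, 138 and 151 without male testosterone replicates 1 and 2, and 245 without male testosterone replicate 3, of which 165 were higher in males and 80 lower. It fell by over 1.5 times without each female library except control replicate 3, and without each male control library. With the replicate number as a block it was 77.

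In the hypothalamus limma found 0 of 13569 genes for sex, with 1347 at an unadjusted p under 0.05, or 9.93%, and a smallest adjusted p of 0.059. The unadjusted count ran from 888 without male control replicate 3 to 2615 without female testosterone replicate 1. Without the library labelled female testosterone hypothalamus replicate 3, 93 genes passed, 88 higher in males and 5 lower. Of the 88, 59 were among the 126 of the nucleus taenia, where 0.83 would be shared by independent lists. The library left out scored among the males on these 126 genes, as given below, so leaving it out favours this overlap. The labels do not say whether both regions came from the same birds, and shared birds would raise the overlap expected by chance. The count was 4 without male control replicate 1, 3 without female testosterone replicate 2 and 1 without male testosterone replicate 2, and library weights gave 1706. With all 12 libraries, 124 of the 126 genes were higher in male hypothalamus, with a median log2 difference of 0.73. Of the 8 genes lower in males in the nucleus taenia, 7 were lower in male hypothalamus too. The median of the 8 was −0.35 there, against −1.44 in the nucleus taenia. For a sex difference that differs between the regions, 0 of 13612 genes passed in limma, with 823 at an unadjusted p under 0.05. That unadjusted count ran from 435 without male control hypothalamus replicate 3 to 2072 without female testosterone hypothalamus replicate 1. The median half-width of the interval was 0.85 on the log2 scale, equal to 1.8-fold. It exceeded the median sex difference of 0.73 that the 126 genes had in the hypothalamus. Regional changes of that size in the sex difference therefore stay open for many genes.

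**Figure D2:**
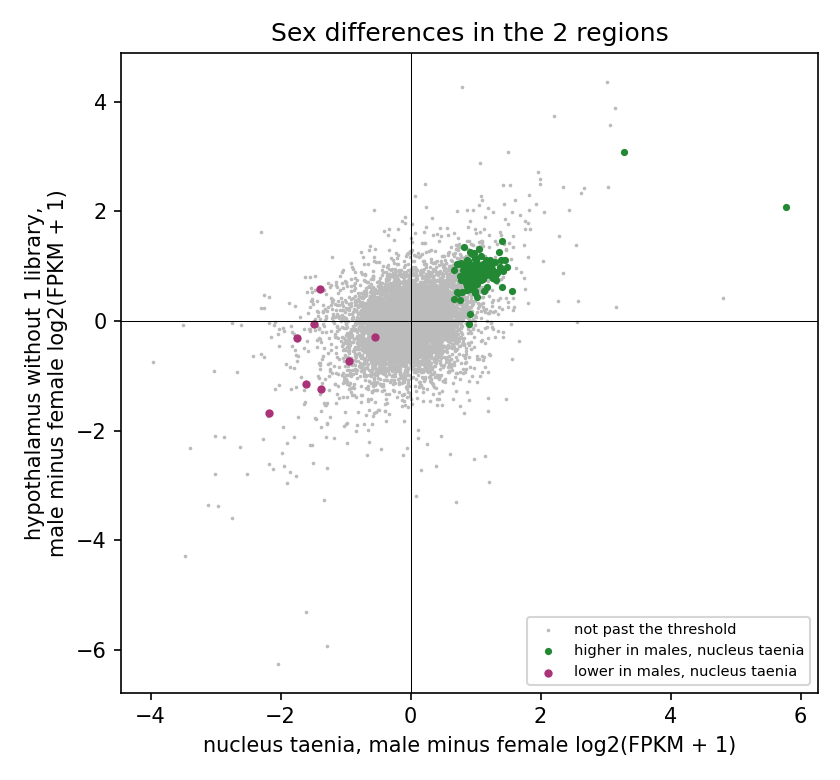
Male minus female log2(FPKM + 1) of each gene in the nucleus taenia (horizontal axis) and in the hypothalamus without female testosterone replicate 3 (vertical axis). Points are genes, coloured by whether they passed the test in the nucleus taenia; the 126 male-higher genes have a median of 0.89 on the vertical axis.

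Each library was scored by the mean log2 value of the 126 genes, less their mean over the 24 libraries. Since the genes were chosen in the nucleus taenia, the hypothalamus libraries took no part in the choice. The male hypothalamus libraries scored 0.19 to 0.73 and 5 of the 6 female ones −0.62 to −0.30. The library labelled female testosterone hypothalamus replicate 3 scored 0.49, within the male range. ENSTGUG00000016397 was at 37.6 FPKM in it, against a mean of 2.62 in the other 5 female hypothalamus libraries.

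**Figure D3:**
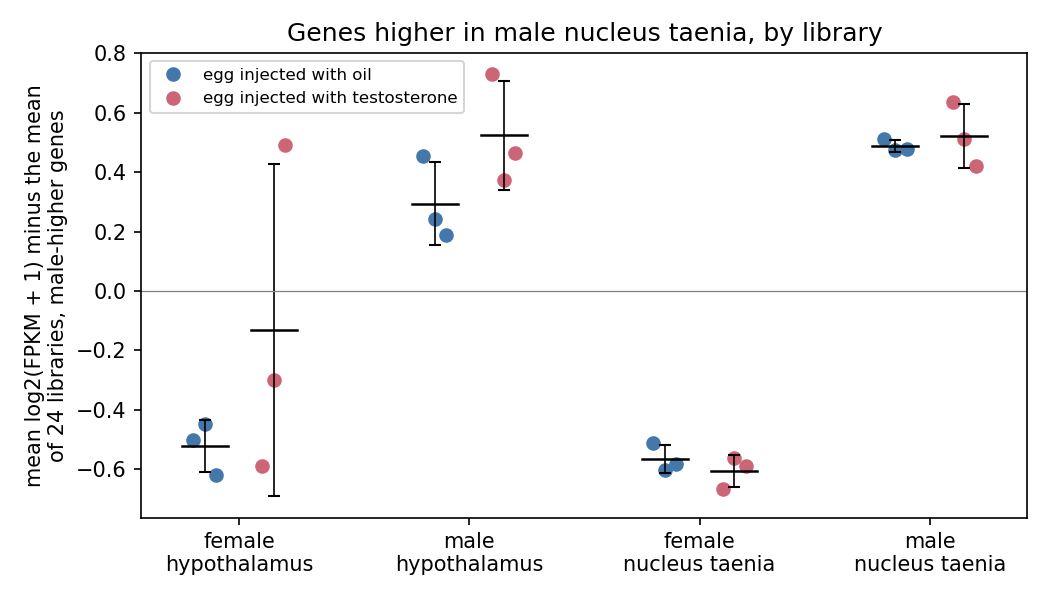
Score of each library on the 126 genes higher in male nucleus taenia (vertical axis, log2 units), by sex and region (horizontal axis) and treatment (colour). Points are libraries, black lines the mean and bars the SD of 3 libraries; the female hypothalamus point at 0.49 is testosterone replicate 3.

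Hypothalamus and nucleus taenia were compared over all 24 libraries. In limma 0 of 13612 genes passed, with 855 at an unadjusted p under 0.05, or 6.28%, and a smallest adjusted p of 0.45. The unadjusted count was 1747 without female testosterone hypothalamus replicate 1 and 1514 without male testosterone nucleus taenia replicate 1. The median half-width of the 95% interval was 0.425 on the log2 scale, equal to 1.34-fold. For 98.1% of genes the whole interval lay within a 4-fold difference either way on the log2(FPKM + 1) scale, which understates the fold of low genes. Libraries of the same region had a mean r of 0.894 and libraries of different regions 0.892, across genes, a difference that did not pass a two-sided permutation test of the region labels (p = 0.695). Same-numbered pairs across regions had a mean r of 0.917. Without these 12 pairs the values were 0.894 and 0.890, and exchanging the regions within a number gave a two-sided exact permutation p of 0.126 over all exchanges, a test added after the data were seen. The count was 1 without female testosterone hypothalamus replicate 2 or male control hypothalamus replicate 1, and 306 with library weights. For a treatment effect that differs between the regions, 0 genes passed in males and 0 in females by limma. At an unadjusted p under 0.05 there were 595 and 374 genes. The median half-width was 1.203 in both, equal to 2.3-fold. The male count ran from 222 without male testosterone nucleus taenia replicate 2 to 1183 without male testosterone nucleus taenia replicate 1, and the female count from 130 without female testosterone hypothalamus replicate 3 to 2206 without female testosterone hypothalamus replicate 1.

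**Figure D4:**
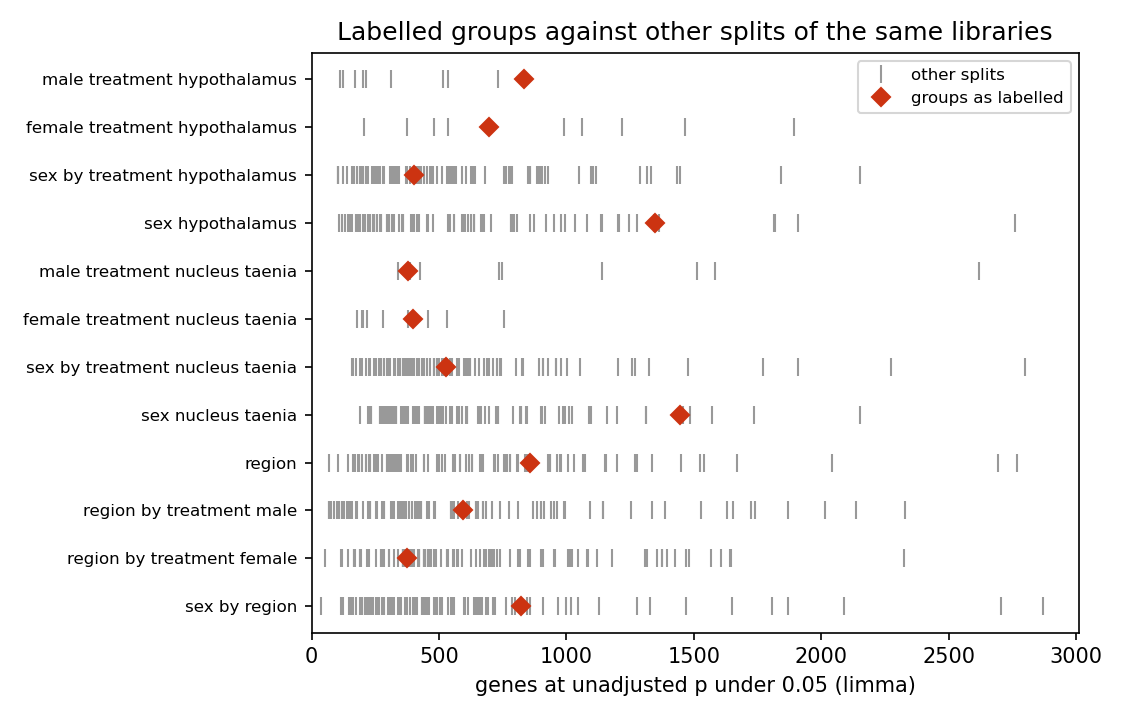
Number of genes at an unadjusted p under 0.05 in limma (horizontal axis) for each contrast (vertical axis), for the groups as labelled (diamonds) and for other splits of the same libraries (ticks). The labelled groups reach 1447 genes for sex in the nucleus taenia and 855 for region.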

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

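Of the tests in this part, the rank correlation, the position of the scores, the counts without 2 libraries and with the bird as a block, the intervals, the splits that part pairs and the relative depth were chosen after the result was seen. Within the 6 libraries of each sex and region, 11 measures gave 42 checks of whether the most extreme library lay far from the rest, and 9 did, where chance gives about 1 in 20, or 2.1. Several measures of 1 library are not independent.

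The library labelled female testosterone hypothalamus replicate 3 was far from the other 5 in total FPKM (1476513, next 983819), median FPKM (7.03, next 11.1), mean r with the other libraries (0.757, next 0.892), score on the male-higher genes (0.492, next −0.301) and ENSTGUG00000016397 (37.6 FPKM, next 6.70). Female control nucleus taenia replicate 3 had a mean r of 0.891, below the 0.903 of the next library. Male testosterone nucleus taenia replicate 2 had a mean r of 0.844, next 0.885, and 5.87 FPKM of ENSTGUG00000015894, next 0.776. Male testosterone hypothalamus replicate 2 had 4.98 FPKM of the same gene, next 1.74.

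The library labelled female testosterone hypothalamus replicate 3 correlated less with the rest than any other library did. A different scale of its values was argued against by the mean Spearman rho of 0.733, which no rescaling changes and which lay below the 0.841 to 0.919 of the others. Over 3806 genes of mean FPKM at least 50 its mean r was 0.561, below the 0.692 to 0.826 of the others. This argues against low depth only if counting noise is small in such genes, and absolute depth, which decides that, is unknown. The rough depth estimate of 0.69, with 3 libraries shallower, also went against low depth. The number of its genes above 0, 14285, was the lowest of all libraries and went the other way. Fewer distinct RNA molecules, degraded RNA or other tissue in the punch may also set it apart; none of these was tested, and no biological explanation was tested.

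The same library lay among the males on the 126 genes higher in male nucleus taenia. Its excess over the other 5 female hypothalamus libraries was 0.98 on the log2 scale. Of 10000 random gene sets matched on expression, 0 reached it (random median −0.34, highest 0.23). This argues against a deviation shared by all genes of like expression. The random sets were not matched on how their genes vary together. A general deviation of the library that moves these 126 genes together therefore stays open. A swap with a male hypothalamus library was argued against, since 0 of the 6 male libraries scored in the range of the other 5 female ones. RNA of a male bird under this label stays open. Its score of 0.492 in the male range of 0.189 to 0.730 is the pattern itself, and on the 8 genes lower in males it scored −0.721, below both the −0.224 to 0.994 of the other 5 female libraries and the −0.646 to 0.123 of the male ones, which decides nothing. A swap with a sample outside these libraries, a mixture, and a real change of these genes in 1 bird stay open too.

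The 2 regions were separated by 0 genes. Too few libraries for large differences was argued against by the simulation, which recovered 90.6% of 4-fold differences, and by the intervals, which lay within 4-fold for 98.1% of genes. Leaving out female testosterone hypothalamus replicate 3 and male testosterone nucleus taenia replicate 2 together gave 0 genes, which argues against these 2 deviant libraries as the cause. Differences between birds stay open: the replicate number as a block gave 0 genes, with 1317 at an unadjusted p under 0.05 against 855 without it, but the numbers are not shown to mark birds. Punches that took in neighbouring tissue, exchanged region labels in part of the libraries, or small regional differences may each remain; without gene names no regional marker could be examined.

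Other splits of the same libraries were counted for each contrast. All 10 were counted for treatment. For the other contrasts 100 were drawn, the labelled one included, of 80000 possible for region and sex by region and 200 for the rest. For sex in the nucleus taenia, 1 of the 100, the labelled one, gave 134 genes, and the highest other drawn gave 3. This argues against chance for that count without excluding it, since the share cannot fall below 1 in 100. At an unadjusted p under 0.05 chance is not argued against, as 6 of the 100 splits reached the real 1447 and the highest other gave 2150. At an unadjusted p under 0.05, chance is not excluded for sex in the hypothalamus (6 of 100 splits reached the real 1347, highest other 2760), region (25, real 855, highest 2768), sex by region (18, real 823, highest 2869), sex by treatment in the hypothalamus (57, real 403, highest 2151) and in the nucleus taenia (46, real 528, highest 2798), or region by treatment in males (39, real 595, highest 2330) and females (74, real 374, highest 2325). Treatment allows only 10 splits, too few for a share under 0.05. In the male hypothalamus 1 split reached the real 833 genes, with 730 the highest other, and in the female hypothalamus 6 reached 697, with 1893 the highest. In the male nucleus taenia 9 reached 378, with 2617 the highest, and in the female nucleus taenia 4 reached 399, with 753 the highest. Of the 4 splits that part every same-numbered pair of the female nucleus taenia, the labelled one gave most, the next giving 281; the other splits leave a same-numbered pair in 1 group. Other splits reached 246 genes past the adjusted threshold for sex in the hypothalamus and 173 for region by treatment in males. They also reached 71 for male treatment, 66 for sex by treatment and 18 for female treatment in the nucleus taenia, and 62 for sex by treatment in the hypothalamus. The labelled groups gave 0 in all of these, and other contrasts with 0 labelled calls reached 1 to 3. Such counts point to a structure of the libraries, and what it is was not tested. The split with 246 genes was the labelled one with female control replicate 2 and male control replicate 1 exchanged, although their scores on the male-higher genes, −0.449 and 0.453, lay with their labelled sexes.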

How the results depend on the processing

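The alternatives added after the data were seen were the 2 deviant libraries left out together, the largest library weight held at 3.5, other scalings of the score and all those of the sex-by-region contrast. Over the 12 contrasts, 227 of 265 alternative counts stayed within 1.5 times the reported count, most of them 0 against 0. Of 264 alternative counts at an unadjusted p under 0.05, 77 moved by more, so those counts are unstable. Pseudocounts, median-ratio scaling, quantile normalization and robust moderation moved no count by more, and the sex count of the nucleus taenia was 122 to 139 under them. Library weights gave 2146 genes for female treatment and 18 for sex by treatment in the hypothalamus, 1706 for sex there and 306 for region. Female testosterone hypothalamus replicate 2 had a weight of 241 among the hypothalamus libraries and 45.1 among all 24. With the largest weight held at 3.5 the female treatment count was 1. A minimum of 5 FPKM gave 1 gene for sex in the hypothalamus, and fitting the 6 libraries alone gave 1 for female treatment there; the cause was not tested.

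Leaving out 1 library of the contrast gave 0 to 17 genes for male and 0 to 3 for female treatment in the hypothalamus. In the nucleus taenia it gave 0 to 4 and 0 to 1. Libraries of the other sex share the spread of a treatment fit and were not left out singly. For sex by treatment the counts were 0 to 1 in either region. For sex they were 0 to 93 in the hypothalamus and 65 to 245 in the nucleus taenia, and for region 0 to 1. Fewer samples lower some counts; the cause of the rises was not tested. The 4 printed genes lost or gained a call in 44 of 166 alternatives and no called gene turned its direction. The sex difference of ENSTGUG00000008528, near 0 in the hypothalamus and not called there, changed sign in 6.

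The replicate number as a block gave 77 genes for sex in the nucleus taenia, where numbers do not pair the libraries (r −0.280 to 0.102), and left the other counts at 0. In the female hypothalamus that ended the 1 call of the unblocked fit of the same 6 libraries, and for male treatment there 1446 genes had an unadjusted p under 0.05, against 1314 without the block. Across regions 10 of 12 same-numbered pairs correlated above 0.1 (r −0.062 to 0.669), and 9 of 12 hypothalamus libraries correlated best with their own number, a hint from the data, not the design. Gene list tests and their alternatives were not run, for lack of gene names. Absolute depth is unknown and limits what low genes can show.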

Other observations

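The test in this part was chosen after the result was seen. Of the 134 genes that differed between the sexes in the nucleus taenia, 126 were higher in males, with a median log2 difference of 1.01. In birds males are ZZ and females ZW, and many Z-linked genes are not fully dosage compensated. A candidate explanation is therefore that many of these genes lie on the Z chromosome. A dose effect predicts a median log2 difference between 0.5 and 1 in libraries that did not choose the genes, and the hypothalamus libraries gave 0.727 with all 12 and 0.89 without the library labelled female testosterone hypothalamus replicate 3. The genes had been chosen for a nucleus taenia difference, which was at least 0.66, so any sex difference shared by the regions could fall near that window. The library left out scored among the males on these genes, so leaving it out raises the median. Neither value therefore tells a dose effect from another shared sex difference. The test is not independent if both regions came from the same birds, and other causes of a difference of that size stay open. Chromosomes were not used here.

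The gene with the highest mean ran from 323.6 to 53759 FPKM over the 24 libraries, a 166-fold range, and was looked at because of that range.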
